A study of Gluconobacter oxydans with 18 samples.

How the data were processed

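Gene expression was measured in 18 cultures of Gluconobacter oxydans, an acetic acid bacterium that oxidises sugars incompletely in its periplasm. Cells from a seed culture were moved into flasks of glucose medium holding 1 of 5 aldehydes or none, shaken at 30 °C, and collected after 4 h. The labels give 1.2 g/L furfural (12.5 mM), 1.5 g/L 5-hydroxymethylfurfural (HMF, 11.9 mM), 0.8 g/L 4-hydroxybenzaldehyde (6.55 mM), 0.8 g/L vanillin (5.26 mM) and 0.9 g/L syringaldehyde (4.94 mM), the molar doses being computed here from the molar masses. Each of the 6 groups had 3 biological replicates, with 1 array per culture and no pooling.

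Cy3-labelled RNA was hybridised to a custom Agilent 1-colour array. The deposited scanner files hold spot intensity from Agilent Feature Extraction, background-subtracted and detrended within each array and not scaled between arrays, with quality marks of 0 or 1 for every spot. Per the file headers the program version was 11.5.1.1, while the submitters' notes give 10.7.3.1. The labelling text names a miRNA array, but the protocol in the files is the one for gene expression and the probes carry gene names. The deposited series table holds log2 intensity with each array's 75th percentile set to 0. Its values for the array's probes were checked against the scanner files, with a correlation of 1 on every array.

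Each array had 15744 spots, of which 536 were controls. The other 15208 spots stood for 2664 probes of 2663 gene names, each probe printed 5 to 10 times. Only 216 of the names were gene symbols and 2447 were GOX identifiers without a description, so functions could be named for the 216 symbols alone. Processed intensities were taken to log2, each array's 75th percentile was subtracted, control spots and spots marked as outliers were left out, and spots were averaged to probes and probes to genes. A probe was kept if it was well above background on every array of at least 1 group, which left 2589 probes and 2588 genes.

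The 18 arrays went into a single fit with a mean per group in limma 3.58.1 (R 4.3.3), followed by empirical Bayes moderation. There were 12 residual degrees of freedom and 4.42 prior degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and the count that also changed at least 2-fold was kept beside it. The comparisons were each aldehyde against control, furfural against HMF, the 3 pairs of phenolic aldehydes, and the mean of the 2 furan aldehydes against the mean of the 3 phenolic aldehydes. All folds are log2 differences with the standard error (SE) from limma, and group levels are log2 signal relative to the 75th percentile with their SD. The number of arrays limits the precision: the median 95% confidence interval reached 0.27 log2 units to each side for a comparison of 3 arrays with 3.

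The comparisons, tests, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each aldehyde against control, the 6 largest rises and 6 largest falls among passing genes with a symbol whose 3 treated arrays all lay beyond the 3 control arrays, up to 3 passing members of each gene list by smallest p, and the largest changes among genes with an identifier only. For comparisons between aldehydes it took the 4 largest changes with a symbol in each direction, and for the shared response the 8 largest mean changes in each direction. The rule asked for genes with an informative annotation, which was read as having a symbol. Of the genes taken by the rule, those whose call ended when 1 array was left out were not named, a choice made after the data were seen.

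Gene lists had been planned as words in product descriptions. The files hold none, so members were filled in from gene symbols after the files were seen and before any group was compared. Of the 17 planned themes, 6 could be filled: protein folding and proteolysis, ribosomal proteins, aminoacyl-tRNA synthetases, flagella, DNA repair and SOS, and fatty acid synthesis. A further 9 lists were added from the symbols present: translation factors, transcription machinery, RNA modification and ribosome assembly, cell wall synthesis, amino acid synthesis, nucleotide synthesis, cofactor synthesis, glycolysis and citrate cycle, and conjugation, type IV secretion and pili. Fatty acid synthesis, with 4 measured genes, was described and not tested, because at least 5 were required. The other 14 lists were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 14 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were run beside it. Every list was drawn from the 216 genes with a symbol, while most other genes had an identifier only. Camera therefore does not separate a list's shift from one common to genes with a symbol.

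Each fit was tested on simulated data with 200 changed genes per comparison. Between 74.6% and 94.0% of 1.5-fold changes, and between 95.5% and 100% of 2-fold changes, were recovered, and false calls made up between 1.57% and 8.59% of the calls of a comparison. A simulated shift of the ribosomal proteins by -0.3 log2 units was found in 20 of 20 simulations with either correlation, while other lists were called 3 times with the preset and 0 times with the estimated correlation. In all these simulations genes varied independently, whereas the correlation estimated for the ribosomal proteins was 0.25. They therefore do not show how often calls are found or false where genes are correlated.

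Alternatives covered background correction (normexp, with the median in place of the mean spot signal, which the files lack), quantile and median scaling, the filter on dim probes, the brightest probe per gene, the deposited series table, limma-trend, the slide as a fixed or random block, single slides, replicate number as a block, only the groups compared, and each array left out in turn. The furan comparison without each phenolic aldehyde in turn, array brightness as a covariate and a normexp correction with the local background limited to each array's 99th percentile were added after seeing the data. Spike-in signals were used only to check the arrays. No reference genome or annotation was used here.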

Results

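The 18 arrays covered untreated cells, cells exposed to the furan aldehydes furfural and HMF, and cells exposed to the phenolic aldehydes 4-hydroxybenzaldehyde, vanillin and syringaldehyde, with 3 cultures in each of the 6 groups. The 5 compounds are the aldehydes that the series title calls typical inhibitors, and the design asks how the transcriptome responds to each. The doses differed between compounds, from 4.94 mM syringaldehyde to 12.5 mM furfural, so differences between aldehydes are differences between those doses as well. The median spot signal per array ran from 996 to 3326, between 92.7% and 98.0% of probes were well above background, and no spot was saturated. The SD of the difference between replicate arrays of a group had a median of 0.25 log2 units, against 0.65 between arrays of different groups. Control, syringaldehyde and vanillin replicates 1 and 2 shared slide 1. Vanillin replicate 3, 4-hydroxybenzaldehyde, HMF and furfural replicate 1 were on slide 2, and furfural replicates 2 and 3 on slide 3. For furfural, HMF and 4-hydroxybenzaldehyde no slide held both treated and control arrays, so their within-slide values could not be had and a fit with slide as a block stands beside them. In that fit the slide 2 term rests on vanillin replicate 3 set against vanillin replicates 1 and 2. The slide 3 term takes up furfural replicates 2 and 3, so the furfural values with the block rest on furfural replicate 1. A normexp background correction was decided by 23 spots of vanillin replicate 3 whose local background exceeded 10 times the array's median. It gave 235 passing genes for furfural, 359 for HMF, 576 for 4-hydroxybenzaldehyde, 1481 for vanillin and 271 for syringaldehyde, against 1040, 1239, 1484, 2078 and 1056 with the local background limited.

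**Figure D1:**
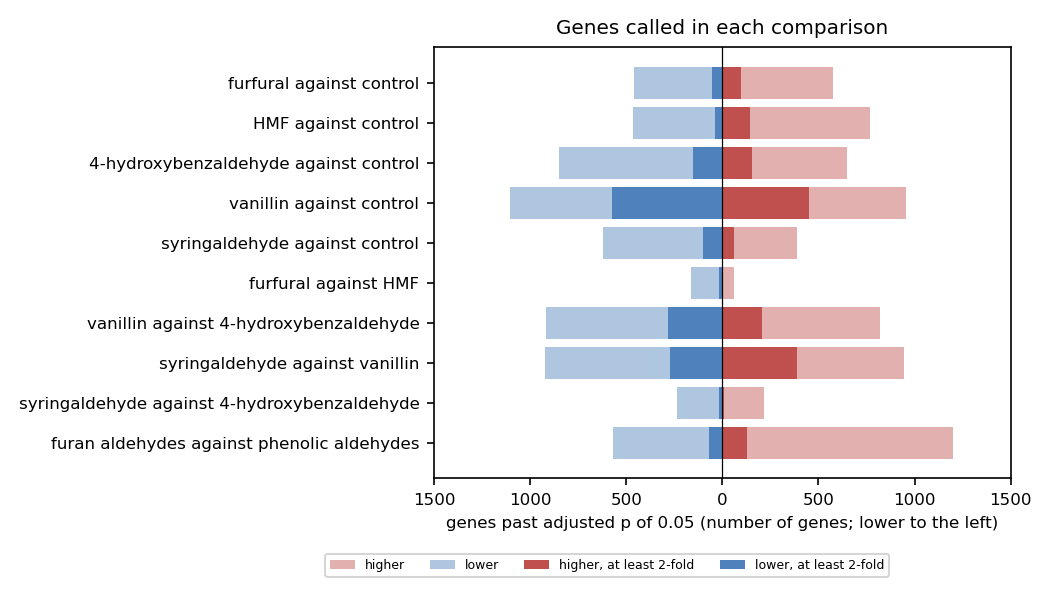
The bars give the number of the 2588 tested genes past an adjusted p of 0.05 in each comparison, higher to the right and lower to the left, with the part changed at least 2-fold in dark colour. Vanillin against control had 2060 such genes, and furfural against HMF had 222.

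With all 5 aldehydes, 207 genes rose in every comparison with control and 210 fell in every one. Among those that rose were hutH, the gene of histidine ammonia-lyase, which degrades histidine (mean log2 fold 1.59 over the 5 aldehydes), tpiA, which encodes the glycolytic triosephosphate isomerase (1.04), uvrC (0.83) and uvrA (0.81), both of nucleotide excision repair, and pqqA, the precursor peptide of the cofactor pyrroloquinoline quinone (0.73). Most of the hutH mean came from 4-hydroxybenzaldehyde, and with no other aldehyde did its rise reach that mean. Those that fell included carB, a subunit of carbamoyl phosphate synthase, which serves arginine and pyrimidine synthesis (-1.14), murD of peptidoglycan synthesis (-1.01), the flagellar gene flgL (-0.95), purH of purine synthesis (-0.88), metX of methionine synthesis (-0.80) and alaS, the alanyl-tRNA synthetase gene (-0.77). The largest mean rises among genes with an identifier only were those of GOX0691 (2.97) and GOX0667 (2.92), and the largest mean fall of a gene above background in all groups was that of GOX1212 (-4.69). GOX2132 was not well above background in any treated group, and its fall was at least 10.9-fold with furfural, at least 11.8-fold with HMF, at least 14.4-fold with 4-hydroxybenzaldehyde, at least 6.22-fold with vanillin and at least 7.39-fold with syringaldehyde. These bounds hold for the background correction used here: with normexp and a limited local background its log2 folds were smaller, -2.76, -2.48, -2.58, -2.13 and -2.40 in the order above.

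Of the 2588 genes, 2397 passed in at least 1 comparison with control, 191 passed in none, and 273 rose with 1 aldehyde and fell with another. At least a 2-fold change in all 5 was seen for 18 genes that rose and 30 that fell. Independent lists as large as those of all passing genes would share 2.36 higher and 2.78 lower genes, beside the 207 and 210 found. Simulated data with no effect and the same control arrays shared 0 and 0. Such data hold almost no passing genes, so that outcome does not test the overlap from shared controls. Across genes, which are not independent replicates, the folds of pairs of aldehydes correlated at 0.53 to 0.88, while the simulations gave 0.50 from the shared controls alone. The simulated folds hold noise only, so 0.50 does not measure what the shared controls add to the measured correlations. For HMF and vanillin, the pair at 0.53, the covariance of the folds was 0.362, against 0.0110 simulated. The covariance of the 4-hydroxybenzaldehyde and vanillin folds was 0.738, against 0.0110 simulated, and that of furfural and HMF was 0.283, against 0.0109. All 5 comparisons used the same 3 control arrays, which cannot be split into separate sets of 2, so part of the excess may rest on them. With slide as a block 143 genes moved the same way in all 5, 87 of them higher. Of the shared genes named, the block ended the calls of hutH with furfural, of uvrA with furfural, HMF and 4-hydroxybenzaldehyde, of flgL with furfural and 4-hydroxybenzaldehyde, and of carB, metX and alaS with furfural and HMF. Some of these folds stayed about as large with the block, such as those of carB (-0.82) and flgL (-0.51) with furfural. Others shrank, such as those of hutH (0.11) and uvrA (0.24) with furfural. All furfural folds with the block rest on furfural replicate 1 and on a slide 2 term from 1 vanillin array.

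Furfural, a furan aldehyde formed from pentoses, raised 576 genes and lowered 460. Of the 216 genes with a symbol, from which every list was drawn, 20 rose and 57 fell. The largest rises among genes with a symbol included those of rpmJ, a ribosomal protein gene (log2 fold 0.85 ± 0.19 SE, n = 3, adjusted p = 0.00257), tpiA (0.84 ± 0.09), aat, whose product attaches leucine or phenylalanine to proteins marked for degradation (0.79), glyQ, a subunit of glycyl-tRNA synthetase (0.78), and nadE, the NAD synthetase gene (0.75). The largest falls of such genes included those of the pilus gene pilN (-1.15 ± 0.21 SE, adjusted p = 0.000469), carB (-0.79), the ribosomal protein gene rplE (-0.71) and the pilus gene pilR (-0.70). With normexp and a limited local background pilN was at -0.756 and glyQ at 0.515. GOX0667 rose 6.02-fold and GOX1212 fell 22.8-fold. At least a 2-fold change was seen for 149 genes.

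Of 47 ribosomal protein genes, 13 fell with furfural and 2 rose (7 and 2 adjusted over the list alone), rplM at -0.52 and rpsI at -0.49, and the list was lower than other genes (median -0.21, camera adjusted p = 0.0214, adjusted p = 0.569 with an estimated correlation). Aminoacyl-tRNA synthetase genes fell in 6 of 14 cases and 1 rose (7 and 1 adjusted over the list alone), with cysS at -0.59, alaS at -0.51 and ileS at -0.41 (adjusted p = 0.0214, and adjusted p = 0.277 with an estimated correlation). Amino acid synthesis had 6 of 15 lower, among them metX (-0.67) and leuD (-0.59), nucleotide synthesis 6 of 13 lower and 1 higher, with purH at -0.64 and ndk at -0.53, and cell wall synthesis 5 of 12 lower, with murD at -0.66 and mraY at -0.51. Each of these 3 had an adjusted p of 0.0214, with an adjusted p = 0.277 with an estimated correlation for amino acid and cell wall synthesis and an adjusted p = 0.405 for nucleotide synthesis. RNA modification and ribosome assembly had 6 of 15 lower, with era at -0.41 and engA at -0.31 (adjusted p = 0.0274, and adjusted p = 0.277 with an estimated correlation). Cofactor synthesis had 5 of 12 higher and 1 lower, with nadE, pqqA (0.65) and pdxA of pyridoxal phosphate synthesis (0.38) among the higher ones. Of 9 DNA repair genes 3 rose (2 adjusted over the list alone), uvrA at 0.65 and uvrC at 0.57, and the list's median of 0.07 turned to -0.02 with slide as a block. Neither of these lists passed as a whole (adjusted p = 0.287 and 0.492).

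Of the remaining lists with furfural, conjugation and pili had 4 of 11 lower and 1 higher, traA (0.55), glycolysis and citrate cycle 2 of 7 in each direction, translation factors 2 of 7 lower with prfA at -0.37, flagella 2 of 13 lower with flgL at -0.53, transcription machinery 1 of 5 lower (nusA, -0.43), and folding and proteolysis 1 of 7 higher (clpS, the adaptor of the ClpAP protease, 0.41). None of these passed. The flagellar list had a positive median (0.13) and a camera direction downwards, which turned to -0.06 and upwards with slide as a block, the folding list a median of -0.09 and a mean of 0.0043, and the glycolysis list a median of -0.16 and a mean of 0.04. Fatty acid synthesis had 1 of 4 lower, fabG (-0.60).

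A fit with slide as a block called 263 genes for furfural, of which 216 had passed the same way without it. The median size of the fold of the 1036 genes was 0.54 without and 0.55 with the block, and the median SE rose from 0.13 to 0.25. Because the slide 3 term takes up furfural replicates 2 and 3, the fit with the block rests on furfural replicate 1. It is not a check with 3 furfural arrays. With the block 27 of the 37 genes named for furfural no longer passed, and only the ribosomal list still did (adjusted p = 0.0363). Quantile normalization ended all 6 list calls of furfural (smallest adjusted p = 0.0526).

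HMF, a furan aldehyde formed from hexoses, raised 768 genes and lowered 463. Of the 216 genes with a symbol 45 rose and 44 fell. Among genes with a symbol, the largest rises included those of rpmJ (log2 fold 1.05 ± 0.19 SE, n = 3, adjusted p = 0.000405), hutH (0.92), pqqA (0.90), lipB, which transfers lipoyl groups to enzymes (0.90), tpiA (0.76) and traA of conjugal transfer (0.76). The largest falls of such genes included those of flgL (-0.81 ± 0.10 SE, adjusted p = 1.52e-05), acpS, which activates acyl carrier protein (-0.59), ilvH of branched-chain amino acid synthesis (-0.58), nusA, a transcription elongation factor (-0.57) and purH (-0.55). GOX0667 rose 4.62-fold and GOX1212 fell 17.2-fold, and 179 genes changed at least 2-fold.

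Aminoacyl-tRNA synthetases had 7 of 14 genes lower and 1 higher with HMF (8 and 1 adjusted over the list alone), with cysS at -0.54 and ileS at -0.52 (camera adjusted p = 0.0228, and adjusted p = 0.256 with an estimated correlation). Cell wall synthesis had 7 of 12 lower, among them murD at -0.53 (adjusted p = 0.0145, and adjusted p = 0.256 with an estimated correlation). Amino acid synthesis had 7 of 15 lower and 1 higher, with hisH at -0.55 and trpD at -0.40, and nucleotide synthesis 5 of 13 lower (1 adjusted over the list alone). Both had an adjusted p of 0.0263, with adjusted p = 0.369 and adjusted p = 0.597 with an estimated correlation, and quantile normalization ended both calls (adjusted p = 0.115 and 0.106). Of 47 ribosomal protein genes 10 rose and 1 fell (9 and 1 adjusted over the list alone), rplC at 0.36 and rplP at 0.40 (list adjusted p = 0.584). The median of that list was 0.10, and with slide as a block it was -0.00347. Cofactor synthesis had 7 of 12 higher and 1 lower, with nadE at 0.57, and DNA repair 3 of 9 higher and 1 lower (the same counts adjusted over the list alone), with uvrA at 0.69, recA, which also controls the SOS response, at 0.57 and uvrC at 0.47. Conjugation and pili had 5 of 11 higher, with pilT at 0.68, and a median of 0.30 that turned to -0.04 with quantile normalization. None of these 3 lists passed (adjusted p = 0.309, 0.602 and 0.400).

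Flagella had 5 of 13 genes higher and 3 lower with HMF (the same adjusted over the list alone), with flgA at -0.48, a median of -0.10 that was 0.01 with slide as a block, and a mean of 0.04. RNA modification had 4 of 15 lower and 2 higher, with era at -0.48, and a median of -0.06 that was 0.03 with the block. Transcription machinery had 1 of 5 in each direction, rho of transcription termination rising by 0.66, glycolysis and citrate cycle 1 of 7 in each direction with pgk at -0.25 (adjusted p = 0.0842 with only these groups fitted), translation factors and fatty acid synthesis 1 lower each, and folding and proteolysis 1 higher. None of the tested ones passed. Medians and camera directions differed in sign for folding (median 0.02, camera downwards) and glycolysis (median 0.07, camera downwards). The folding median turned to -0.16 with the block and the glycolysis median to -0.15 with quantile normalization.

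The fit with slide as a block called 566 genes for HMF, 495 of them shared with the fit without it. The median size of the fold was 0.55 without and 0.58 with the block, the median SE 0.13 and 0.22. With the block 17 of the 34 genes named for HMF no longer passed, and the lists no longer did (smallest adjusted p = 0.0800). Quantile normalization moved the split of higher and lower genes to 639 and 643.

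4-Hydroxybenzaldehyde raised 647 genes and lowered 852. The split was 728 higher and 763 lower with median scaling, and 774 and 804 with quantile normalization. Of the 216 genes with a symbol 32 rose and 104 fell in the main fit. The largest rise among genes with a symbol was that of hutH, 24.1-fold (log2 fold 4.59 ± 0.12 SE, n = 3, adjusted p = 1.1e-14), from a level of -3.88 ± 0.17 (SD) in control to 0.71 ± 0.04. Also higher were clpS (1.34 ± 0.10), lpxC, which commits precursors to lipid A synthesis (1.31), tpiA (1.14), hemH, the ferrochelatase that completes haem (1.06), and anmK, which recycles a peptidoglycan sugar (1.05). The largest falls of genes with a symbol included those of the pilus and conjugation genes pilN (-1.90 ± 0.21, adjusted p = 8.72e-07), pilL (-1.67), trbG (-1.39), pilR (-1.32) and dotH (-1.29), and of fabG, a reductase of fatty acid synthesis (-1.33). With normexp and a limited local background the falls of these pilus and conjugation genes still passed and were smaller. They were then -1.10 for pilN, -1.10 for pilL, -0.50 for trbG, -0.87 for pilR and -0.64 for dotH. GOX0691 rose by 4.17 on the log2 scale and GOX1212 fell 33.3-fold.

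**Figure D2:**
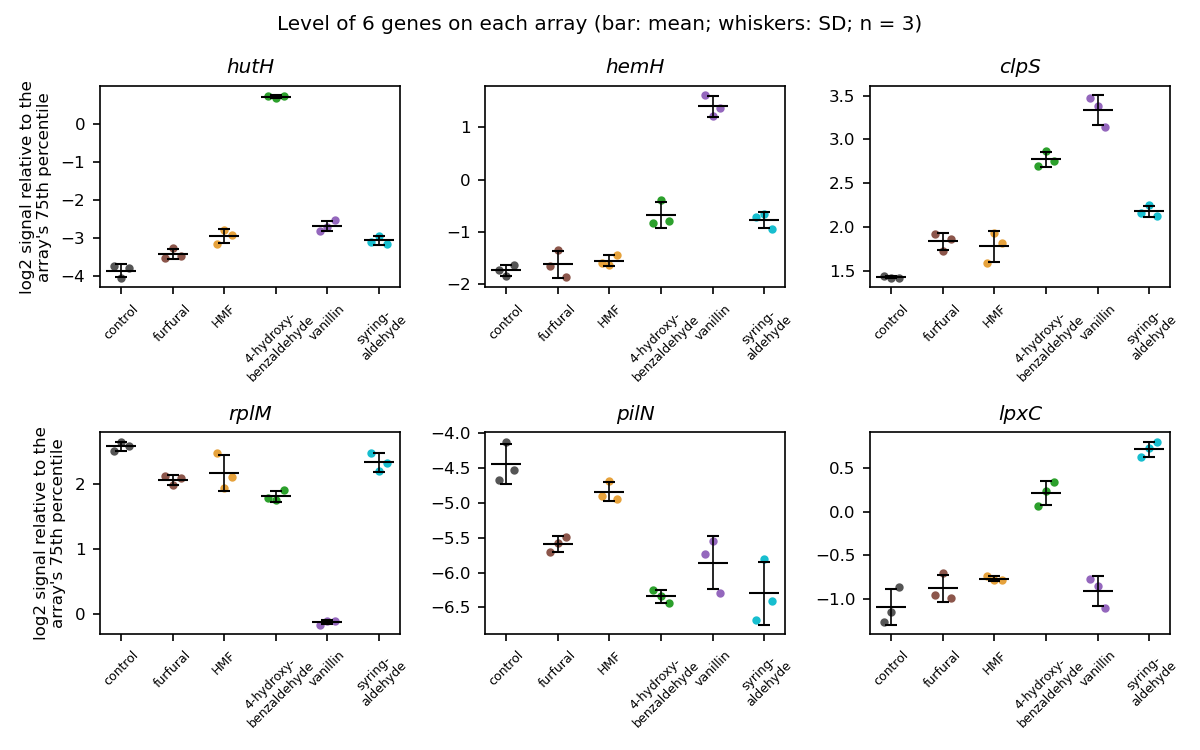
Each panel plots 1 gene's log2 signal relative to the array's 75th percentile on the 18 arrays by group, with a bar at the mean and whiskers of 1 SD (n = 3). The mean of hutH is 0.71 with 4-hydroxybenzaldehyde and -3.88 in control, and the mean of rplM is -0.13 with vanillin and 2.58 in control.

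Conjugation, type IV secretion and pili had 9 of 11 genes lower with 4-hydroxybenzaldehyde and none higher, with repC, a plasmid replication gene, at -1.28 (median -1.28, camera adjusted p = 0.0244, and adjusted p = 0.403 with an estimated correlation). With normexp and a limited local background 9 genes were lower. The list's median was then -0.60, and it no longer passed (adjusted p = 0.0529). Of 47 ribosomal protein genes 18 fell and none rose (14 adjusted over the list alone), rpmB at -0.78, rplM at -0.77 and rpsI at -0.74 (adjusted p = 0.0281, and adjusted p = 0.554 with an estimated correlation). Amino acid synthesis had 10 of 15 lower, with carB at -1.21 and hisD at -0.89 (adjusted p = 0.00743, and adjusted p = 0.391 with an estimated correlation). RNA modification had 10 of 15 lower, with tgt and queA, both of queuosine formation in tRNA, at -0.89 and -0.89, and nucleotide synthesis 9 of 13 lower and 1 higher, with dcd at -0.99, purU at -0.98 and purH at -0.96. Each of these had an adjusted p of 0.0281, with adjusted p = 0.391 and adjusted p = 0.403 with an estimated correlation.

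Lists that did not pass with 4-hydroxybenzaldehyde included aminoacyl-tRNA synthetases with 9 of 14 lower and 2 higher (10 and 2 adjusted over the list alone, adjusted p = 0.0632), with aspS at -0.84 and thrS at -0.70, cell wall synthesis with 8 of 12 lower and 1 higher, murD at -1.03 and murE at -0.76 (adjusted p = 0.0632), and translation factors with 4 of 7 lower, infA at -0.83 (adjusted p = 0.0690). Cofactor synthesis had 6 of 12 higher and 3 lower, with thiG and thiE of thiamine synthesis at 0.97 and 0.79. Flagella had 4 of 13 higher and 2 lower (3 and 1 adjusted over the list alone), with fliM at 0.65 and flgL at -0.56, DNA repair 3 of 9 in each direction (the same adjusted over the list alone), with uvrC at 0.96 and uvrA at 0.88 higher, and folding and proteolysis 2 of 7 in each direction (3 lower adjusted over the list alone), with clpX at 0.36. Glycolysis and citrate cycle had 4 of 7 lower, with fumC at -1.11 and eno at -0.45, and 2 higher, transcription machinery 1 of 5 lower, and fatty acid synthesis 3 of 4 lower. With normexp and a limited local background fumC was at -0.69. The DNA repair list had a median of -0.09, which was 0.05 with slide as a block, and a mean of 0.14, the folding list a median of 0.27 that was -0.21 with the block, and the glycolysis list a median of -0.21 and a camera direction upwards.

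A total of 306 genes changed at least 2-fold with 4-hydroxybenzaldehyde. The fit with slide as a block called 870 genes, 784 of them shared with the 1499 without it, with a median fold of 0.59 without and 0.64 with the block and a median SE of 0.13 and 0.22. With the block 4 of the 44 genes named for this aldehyde no longer passed, the RNA modification list ended at an adjusted p of 0.0953, and translation factors passed (adjusted p = 0.0316).

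Vanillin, which carries 1 methoxy group more than 4-hydroxybenzaldehyde, changed the most genes of the 5, with 957 higher and 1103 lower and 1022 changed at least 2-fold (450 higher and 572 lower). The balance turned to 1154 higher and 962 lower with median scaling and to 1067 and 1031 with quantile normalization. Of the 216 genes with a symbol, from which every list was drawn, 31 rose and 165 fell in the main fit. Among genes with a symbol, the largest rises included those of hemH (3.13 ± 0.15 SE, 8.74-fold, n = 3, adjusted p = 7.35e-12), anmK (2.53), glyQ (1.93), clpS (1.90), thiG (1.82) and tpiA (1.63). The largest falls of such genes included those of the ribosomal protein genes rplM (-2.71 ± 0.12 SE, 6.55-fold lower, adjusted p = 2.55e-12) and rpmB (-2.61), uppP, a phosphatase that recycles the lipid carrier of cell wall synthesis (-2.55), engB, a GTPase of ribosome assembly (-2.52), hisD of histidine synthesis (-2.50) and aspS, the aspartyl-tRNA synthetase gene (-2.46). GOX0667 rose 15.8-fold and GOX1212 fell 24.6-fold.

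Of 47 ribosomal protein genes 46 fell with vanillin and none rose (47 adjusted over the list alone), with a median of -1.14 (camera adjusted p = 8.36e-09, and adjusted p = 0.135 with an estimated correlation). Amino acid synthesis had 15 of 15 lower (median -1.70, adjusted p = 6.47e-05), with carB at -2.37 and ilvH at -2.06, and RNA modification and ribosome assembly 13 of 15 lower, with tgt at -2.23 and engA at -1.96 (adjusted p = 0.000591). Both had an adjusted p = 0.0975 with an estimated correlation. Nucleotide synthesis had 13 of 13 lower, with ndk at -2.37 and purU at -2.26 (adjusted p = 0.000336), aminoacyl-tRNA synthetases 12 of 14 lower and 2 higher (the same adjusted over the list alone), with alaS at -1.84 (adjusted p = 0.00608), and translation factors 6 of 7 lower, with infA at -1.81 and prfA at -1.62 (adjusted p = 0.0287). Each of these 3 had an adjusted p = 0.135 with an estimated correlation. Cell wall synthesis had 10 of 12 lower and 1 higher, with murD at -2.04 (adjusted p = 0.0192, and adjusted p = 0.163 with an estimated correlation), and flagella 10 of 13 lower and 1 higher (the same adjusted over the list alone), with flgL at -2.14 and flgA at -1.36 (adjusted p = 0.0349, and adjusted p = 0.222 with an estimated correlation). Quantile normalization ended the flagellar call.

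Folding and proteolysis had 5 of 7 genes higher and 1 lower with vanillin (the same adjusted over the list alone), the protease subunit gene clpP rising by 1.04 and tig, the trigger factor that assists new proteins at the ribosome, falling by 2.15 on the log2 scale (list adjusted p = 0.137). DNA repair had 4 of 9 in each direction (the same adjusted over the list alone), with uvrC at 1.60, uvrA at 1.32 and recF at -0.90. Cofactor synthesis had 6 of 12 higher and 5 lower, with hemH and thiG higher and ispG of isoprenoid synthesis at -1.14. Conjugation and pili had 7 of 11 lower, with repC at -1.85 and pilN at -1.41, and traA higher at 1.04. With normexp and a limited local background 4 of them were lower and 1 higher, and the list's median went from -0.61 to -0.12. Transcription machinery had 4 of 5 lower, with rho at -1.11, glycolysis and citrate cycle 4 of 7 lower and 2 higher, with fumC at -1.98, pgk at -1.13 and tpiA higher, and fatty acid synthesis 4 of 4 lower, with fabG at -1.57 and acpP at -1.46. None of the 5 tested lists other than folding and proteolysis passed (adjusted p from 0.166 to 0.514).

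Within slide 1, which held the 3 control arrays and vanillin replicates 1 and 2, 1947 genes passed, and all 8 lists did. Scaling by the median moved the median fold of all genes with vanillin from -0.08 to 0.12, and the median of the ribosomal proteins relative to that of all genes was -1.06. The folds of pilN, repC and fumC were positive and did not pass with normexp (0.93, 1.11 and 0.74), and when the local background was limited as well they passed at smaller falls (-0.64, -0.54 and -0.83).

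**Figure D3:**
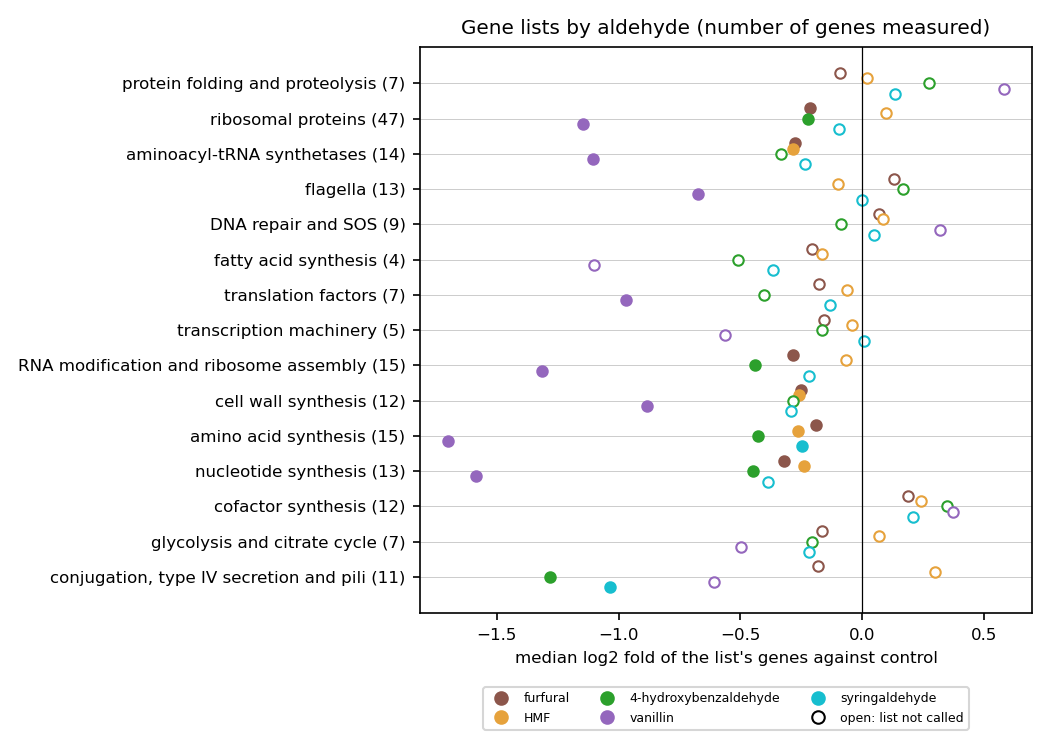
Each point is the median log2 fold against control of the genes of 1 list with 1 aldehyde, filled where camera passed with the preset correlation and open where it did not or was not run, with the number of genes measured in brackets. The vanillin medians of amino acid synthesis (-1.70), nucleotide synthesis (-1.59) and RNA modification (-1.31) lie furthest to the left, and with an estimated correlation no list passed for any aldehyde.

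Syringaldehyde, with 2 methoxy groups, raised 386 genes and lowered 622, and 161 changed at least 2-fold. Of the 216 genes with a symbol 22 rose and 67 fell. Among genes with a symbol the largest rise was that of lpxC (1.81 ± 0.12 SE, 3.51-fold, n = 3, adjusted p = 3.73e-09), followed by lipB (1.04), hemH (0.96), tpiA (0.85), glpD, a glycerol-3-phosphate dehydrogenase gene (0.82), and hutH (0.80). Falls among such genes included those of the conjugation and pilus genes pilN (-1.85 ± 0.21 SE, adjusted p = 2.52e-06), pilL (-1.72), trbN (-1.30), pilR (-1.28), trbG (-1.16) and dotH (-1.04). GOX0691 rose 8.95-fold and GOX1212 fell 35.2-fold.

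Conjugation, type IV secretion and pili had 9 of 11 genes lower and 1 higher with syringaldehyde, with repC at -0.93 (median -1.04, camera adjusted p = 0.0178, and adjusted p = 0.489 with an estimated correlation). Amino acid synthesis had 9 of 15 lower, with carB at -0.91, ilvH at -0.68 and hisD at -0.57 (adjusted p = 0.0204, and adjusted p = 0.489 with an estimated correlation). The other lists did not pass. Nucleotide synthesis had 7 of 13 lower and 1 higher, with dcd at -0.89 and purH at -0.50, cell wall synthesis 6 of 12 lower and 2 higher, with murD at -0.77, murE at -0.60 and murB at -0.42, and RNA modification 5 of 15 lower, with tgt at -0.47 and era at -0.45, each with an adjusted p of 0.113. Aminoacyl-tRNA synthetases had 6 of 14 lower and 2 higher (7 and 2 adjusted over the list alone), with thrS at -0.47, and ribosomal proteins 4 of 47 lower (none adjusted over the list alone), with rplU at -0.58 and a median of -0.09. Fatty acid synthesis had 3 of 4 lower, with fabG at -0.97, translation factors 3 of 7 lower, with infA at -0.47, and glycolysis and citrate cycle 3 of 7 lower, with fumC at -0.88, and 2 higher. Cofactor synthesis had 5 of 12 higher and 3 lower, with pqqA at 0.57. DNA repair had 2 of 9 higher, uvrC at 0.57 and uvrA at 0.53, and 1 lower (3 and 1 adjusted over the list alone), and folding and proteolysis clpS at 0.75 higher and 2 of 7 lower, with the chaperonin gene groEL at -0.57 (2 and 2 adjusted over the list alone). Flagella had 1 of 13 lower, flgL at -0.70, and transcription machinery 1 of 5 lower, with a positive median and mean (0.01 each) and a fry direction downwards. Within slide 1, which held all 6 arrays of this comparison, 858 genes passed. With normexp and a limited local background the conjugation list no longer passed (median -0.34, adjusted p = 0.126). Nor did trbG (-0.26), dotH (-0.34) and repC (-0.33). The genes pilN (-0.90), pilL (-0.98), trbN (-0.63), pilR (-0.72) and fumC (-0.46) still passed in that setting, at smaller falls. Quantile normalization moved the split of higher and lower genes to 570 and 554.

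HMF differs from furfural by a hydroxymethyl group, and the doses were 11.9 and 12.5 mM. In furfural-treated cells 60 genes were higher and 162 lower than in HMF-treated cells, 21 of them at least 2-fold. Of the 216 genes with a symbol 4 were higher and 23 lower. The ribosomal protein gene rpsI was lower with furfural (-0.69 ± 0.11 SE, n = 3, adjusted p = 0.000487) and ilvH was higher (0.54 ± 0.10, adjusted p = 0.0018). Of 47 ribosomal protein genes 10 were lower with furfural and none higher (13 adjusted over the list alone, median -0.30). With quantile normalization 4 were lower (median -0.18), and with median scaling 4 were (median -0.28). Of 11 conjugation and pilus genes 4 were lower and none higher (median -0.64, -0.37 with quantile normalization). With normexp and a limited local background 2 of them were lower (median -0.45). No gene of the lists for aminoacyl-tRNA synthetases, flagella, DNA repair, folding, nucleotide synthesis or cofactor synthesis passed. Of the 2366 genes that did not pass, 2310 had a 95% confidence interval of the difference within 2-fold. The count moved with the arrays and the fit: within slide 2, which held furfural replicate 1 and the 3 HMF arrays, 46 genes passed, with neither rpsI (-0.67) nor ilvH (0.63) among them. The single furfural array of that fit was assumed to vary like the other groups, and the fit with slide as a block rests on the same furfural array. In other fits 58 genes passed with slide as a block, 138 with only these groups fitted, and 102 without furfural replicate 3. The count was 146 without furfural replicate 1, 144 without furfural replicate 2 and 144 without HMF replicate 3, and quantile normalization split the genes into 148 higher and 161 lower.

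Vanillin differs from 4-hydroxybenzaldehyde by a methoxy group, and the doses were 5.26 and 6.55 mM. With vanillin 819 genes were higher and 915 lower, 486 at least 2-fold. Of the 216 genes with a symbol 26 were higher and 153 lower. Among genes with a symbol the largest difference was in hutH, which was 10.6-fold lower with vanillin (-3.41 ± 0.12 SE, n = 3, adjusted p = 1.38e-12), and hemH (2.07), anmK (1.48), glyQ (1.02) and thiG (0.85) were higher. Lower with vanillin were uppP (-1.97), rplM (-1.94) and rpmB (-1.83). All 47 ribosomal protein genes were lower (47 adjusted over the list alone, median -0.92), as were 13 of 13 of nucleotide synthesis, 14 of 15 of amino acid synthesis, 11 of 14 aminoacyl-tRNA synthetases with 1 higher (the same adjusted over the list alone) and 10 of 13 flagellar genes (10 adjusted over the list alone), while 5 of 7 folding and proteolysis genes (5 adjusted over the list alone) and 6 of 11 conjugation and pilus genes were higher. In these 2 lists 1 and 2 genes were lower, and the medians were 0.56 and 0.46. With quantile normalization 3 and 5 genes were higher (medians 0.26 and 0.20), and with median scaling 6 and 9 (medians 0.71 and 0.62). Of the 854 genes that did not pass, 818 had a 95% confidence interval within 2-fold. Within slide 2, which held vanillin replicate 3 and the 3 arrays of 4-hydroxybenzaldehyde, 1416 genes passed, with the single vanillin array assumed to vary like the other group. Scaling by the median moved the median of all genes from -0.00277 to 0.15. It moved the split of higher and lower genes to 1087 and 764.

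Syringaldehyde differs from vanillin by a further methoxy group, and the doses were 4.94 and 5.26 mM. With syringaldehyde 947 genes were higher and 920 lower than with vanillin, 661 at least 2-fold. Of the 216 genes with a symbol 156 were higher and 34 lower. Among the higher genes were rplM, rpmB, engB and uppP, which had been among the largest falls of genes with a symbol with vanillin, with rplM at 2.46 ± 0.12 SE (n = 3, adjusted p = 4.29e-11), rpmB at 2.30, engB at 2.30 and uppP at 2.26. Lower with syringaldehyde were hemH (-2.17 ± 0.15 SE, adjusted p = 1.6e-09), anmK (-1.96), glyQ (-1.45) and thiG (-1.44). All 47 ribosomal protein genes were higher (47 adjusted over the list alone, median 1.17), as were 15 of 15 of amino acid synthesis and 13 of 13 of nucleotide synthesis, while 6 of 7 folding and proteolysis genes were lower and 1 higher (the same adjusted over the list alone). Within slide 1, which held the 3 syringaldehyde arrays and vanillin replicates 1 and 2, 1682 genes passed. Scaling by the median moved the median of all genes from -0.05 to -0.21. It moved the split to 775 higher and 1175 lower.

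Syringaldehyde and 4-hydroxybenzaldehyde, which lacks both methoxy groups, differed in fewer genes, 216 higher and 237 lower with syringaldehyde and 30 at least 2-fold, at doses of 4.94 and 6.55 mM. Among genes with a symbol 29 were higher and 15 lower with syringaldehyde. The gene hutH was 13.8-fold lower with syringaldehyde (-3.79 ± 0.12 SE, n = 3, adjusted p = 1.66e-13), and clpS (-0.60) and fliM, a flagellar motor switch gene (-0.59), were lower as well. The genes purU (0.62 ± 0.10, adjusted p = 0.000545), glmU, which makes a cell wall precursor (0.52), and rplM (0.52) were higher. Of 47 ribosomal protein genes 6 were higher (5 adjusted over the list alone), of 13 flagellar genes 4 were lower (6 adjusted over the list alone), and none of the 11 conjugation and pilus genes passed. Of the 2135 genes that did not pass, 2109 had a 95% confidence interval of the difference within 2-fold. No slide held both groups, and with slide as a block 99 genes passed, 74 of them shared, with purU, glmU and rplM no longer passing (adjusted p = 0.183, 0.0683 and 0.169). Their log2 folds were then 0.44, 0.52 and 0.55, while the median SE over all genes rose from 0.13 to 0.22. The count was 203 without 4-hydroxybenzaldehyde replicate 2, 285 without its replicate 3 and 275 without syringaldehyde replicate 3.

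The furan aldehydes as a family, at 12.5 and 11.9 mM, were set against the phenolic aldehydes at 4.94 to 6.55 mM. With the furans 1201 genes were higher and 570 lower, and 197 differed at least 2-fold. Of the 216 genes with a symbol 147 were higher and 22 lower. The SE and adjusted p of this comparison come from the spread of replicate arrays within each aldehyde. They do not measure the spread between aldehydes of a family, so they speak for these 5 compounds only. The median of all genes was 0.16 in this comparison and 0.03 with median scaling, which gave 926 higher and 831 lower genes, while quantile normalization gave 925 and 843. Higher with the furans were repC (1.49 ± 0.08 SE, adjusted p = 1.21e-10), rpmB (1.31), pilL (1.27) and dotH (1.22), and lower were anmK (-1.61 ± 0.12 SE, adjusted p = 7.86e-09), hemH (-1.57), hutH (-1.51) and clpS (-0.95). Of 11 conjugation and pilus genes 9 were higher with the furans (median 0.95, 0.81 with median scaling, and 0.35 with normexp and a limited local background, where repC was at 0.57, pilL at 0.73 and dotH at 0.54), and of 47 ribosomal protein genes 42 were (45 adjusted over the list alone, median 0.43), with 33 higher under median scaling. Amino acid synthesis had 12 of 15 higher and nucleotide synthesis 10 of 13, and folding and proteolysis had 3 of 7 lower and 1 higher (the same adjusted over the list alone). Single phenolic aldehydes carried part of these values: without vanillin, a setting added after seeing the data, 1431 genes passed and 14 of 47 ribosomal protein genes were higher (median 0.10). In that setting 7 of 15 of amino acid synthesis and 5 of 13 of nucleotide synthesis were. There rpmB was at 0.63, hemH at -0.86 and anmK at -1.04. The folding list's median then turned from -0.22 to 0.08, while 10 of 11 conjugation and pilus genes were higher. Without 4-hydroxybenzaldehyde hutH was at -0.31. Slide 2 held no syringaldehyde array, so the comparison within it set the furans against 4-hydroxybenzaldehyde and vanillin only. Within slide 2, which held furfural replicate 1, the HMF and 4-hydroxybenzaldehyde arrays and vanillin replicate 3, 1523 genes passed, with the single furfural and vanillin arrays assumed to vary like the other groups.

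Spike-in RNA, added in known amounts and not used for the comparisons, separated the groups into those of low and high signal. Its mean log2 signal relative to the 75th percentile was -1.83 ± 0.25 (SD, n = 3) in control, -1.94 ± 0.50 with syringaldehyde and -1.87 ± 0.39 with vanillin, and -0.32 ± 0.28 with 4-hydroxybenzaldehyde, 0.44 ± 0.29 with HMF and 0.14 ± 0.27 with furfural. Each of the last 3 groups differed from control with an exact permutation p of 0.1 (two-sided), the smallest that 3 arrays against 3 can give. The low group ran from -2.48 to -1.46 and the high group from -0.57 to 0.67.

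**Figure D4:**
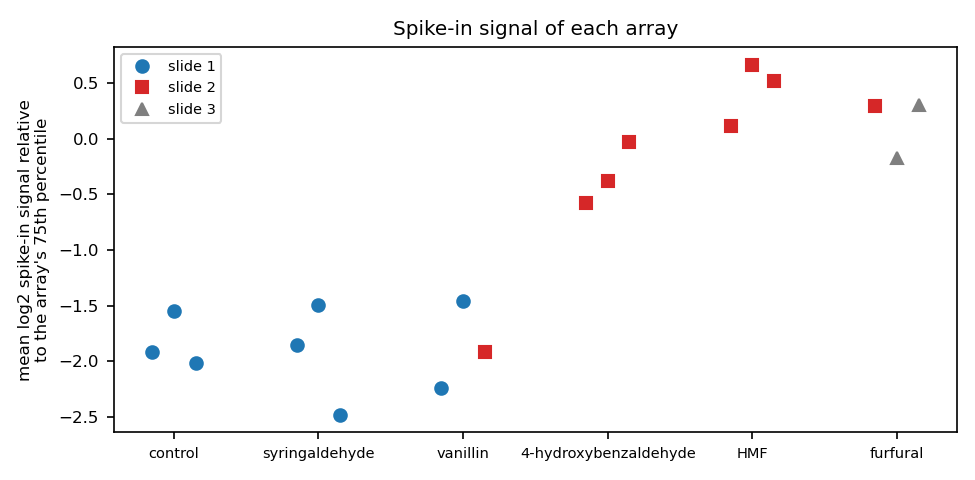
Each point is the mean log2 spike-in signal of 1 array relative to its 75th percentile, by group, with the shape and colour giving the slide. Vanillin replicate 3, on slide 2, lies at -1.92 among the low arrays, while the other arrays of slides 2 and 3 lie at -0.57 or above.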

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

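The tests chosen only after the result was seen were the spike-in signal by slide, the comparison of 571 shared genes with syringaldehyde for slide and for set, the comparison of HMF with 4-hydroxybenzaldehyde within slide 2, the vanillin count without its dimmest array set against 4-hydroxybenzaldehyde in the same fit, and the count of changes of at least 2-fold with array brightness as a covariate, and the covariate itself was added after seeing the data.

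Spike-in RNA, a signal that no comparison used, lay above the control level of -1.83 with 4-hydroxybenzaldehyde (-0.325), HMF (0.436) and furfural (0.142), as log2 signal relative to the 75th percentile. Vanillin replicate 3, hybridised on slide 2, had -1.92 and lay between vanillin replicates 1 (-2.24) and 2 (-1.46) of slide 1. That is 1 array, and no other group had arrays both on slide 1 and on another slide, so slide and group cannot be told apart for this signal. A difference in labelling or in the amount of RNA between sets of arrays stays open as well, because the labels give neither. No biological explanation was tested.

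Furfural, HMF and 4-hydroxybenzaldehyde had at least 1036 called genes each against control, on other slides and with a higher spike-in signal than the control arrays, and for 571 genes called the same way in all 3 comparisons, slide and set are argued against as the whole source: 11 of them (1.93%) were called the same way in all 3 against syringaldehyde, which shares the control's slide and set (35 with furfural, 124 with HMF and 133 with 4-hydroxybenzaldehyde taken singly, for which both stay open), and their median fold in that direction was 0.06 with furfural, 0.07 with HMF and 0.19 with 4-hydroxybenzaldehyde against syringaldehyde, after 0.58, 0.59 and 0.70 against control. Of the 1231 genes called with HMF 435, and of the 1499 called with 4-hydroxybenzaldehyde 823, passed the same way against the other of these 2 aldehydes. All 6 arrays of that comparison were on slide 2, so the 2 aldehydes differed in these genes apart from slide. It held no control array and the other aldehyde may have made the difference, so it cannot decide on slide for the calls against control. With slide as a block 200 and 540 of these genes passed as well. For the genes outside the 571, furfural's included, slide and aldehyde cannot be told apart. With slide as a block 216 genes called with furfural, 495 with HMF and 784 with 4-hydroxybenzaldehyde passed the same way. Slide terms fitted beside the groups passed jointly in 6 genes (211 at an unadjusted p under 0.05), under the bound set beforehand. That bound was wrongly chosen, because the slide 2 term rests on 1 vanillin array. The slide 3 term takes up furfural replicates 2 and 3, so furfural's values with the block also rest on furfural replicate 1. The block moved the median fold of the called genes from 0.54 to 0.55 with furfural, from 0.55 to 0.58 with HMF and from 0.59 to 0.64 with 4-hydroxybenzaldehyde. The median SE rose from 0.13 to 0.25, 0.22 and 0.22. For the genes whose call ended the median fold went from 0.49 to 0.45, 0.47 to 0.42 and 0.46 to 0.37. Of all called genes 35, 19 and 32 changed sign. Set and aldehyde cannot be told apart for the genes outside the 571 either: the split of the 6 groups by set called 1378 genes and the highest of the 10 splits 1899, a bound that was wrongly chosen too, because vanillin's wide folds decide these counts, with 1034, 1078, 1378 and 1546 genes for the splits with vanillin beside control and 1563 or more for the others.

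Vanillin called the most genes of the 5 aldehydes, and its replicate 1 was the dimmest of the 18 arrays (median signal 996), while replicates 2 (1743) and 3 (1575) lay within the range of the others. A single vanillin array is argued against, since the lowest count without 1 of them was 2017, against 1499 for the next aldehyde. With array brightness as a covariate vanillin had 2138 genes and the next aldehyde 1605, which lies between the bounds set beforehand, so that a part of the count cannot be told apart from array brightness. As the whole source brightness is argued against, since without the dim replicate 1 vanillin had 2020 genes and 4-hydroxybenzaldehyde 1509 (counts ranged over at most 318 with single arrays left out), and for changes of at least 2-fold the covariate left 1047 genes with vanillin and 323 with the next aldehyde. The aldehyde and its dose stay open as the biological explanation, untested apart from each other, because each aldehyde was used at 1 dose.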

How the results depend on the processing

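The tests chosen only after the result was seen were array brightness as a covariate, normexp with the local background limited, and the furan comparison without each phenolic aldehyde in turn. Counts within 1.5 times those reported were found for all 10 comparisons with median scaling, with quantile normalization, without the filter on dim probes, with probes above background on all arrays, with the brightest probe per gene, with the deposited series table, with limma-trend, with the slide as a random block, with the replicate block and with normexp with a limited background. Vanillin against control and syringaldehyde against vanillin stayed within that factor in every setting run. The replicate block gave 1103 genes for furfural, 1264 for HMF, 1546 for 4-hydroxybenzaldehyde, 2091 for vanillin and 1056 for syringaldehyde, although replicate numbers did not pair the arrays as a whole, since 20 of 45 pairs correlated above 0.1 and 6 of 18 arrays correlated best with their own number. All 3 pairs did for control with 4-hydroxybenzaldehyde and for control with syringaldehyde. Depth was limited by signal over background: between 1 and 4 passing genes per aldehyde had only the control or only the treated arrays above background.

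With normexp the counts were 235 for furfural, 359 for HMF, 576 for 4-hydroxybenzaldehyde, 271 for syringaldehyde, 13 for furfural against HMF, 1137 for vanillin against 4-hydroxybenzaldehyde, 76 for syringaldehyde against 4-hydroxybenzaldehyde and 812 for furans against phenolics. The source was 23 spots of vanillin replicate 3, whose local background had an SD of 3307.15 against at most 10.4 on the other arrays, and limiting it returned all 10 counts to within 1.5 times those reported. Of 233 named values 28 were then over 1.5 times smaller, mostly those of conjugation and pilus genes. With normexp 101 of 233 named values kept their direction and no longer passed, and the vanillin log2 folds of fumC, repC and pilN turned to 0.74, 1.11 and 0.93.

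With the slide as a fixed block the counts were 263 for furfural, 566 for HMF, 870 for 4-hydroxybenzaldehyde, 58 for furfural against HMF, 99 for syringaldehyde against 4-hydroxybenzaldehyde, 16 for list calls and 143 for the shared response, as the SE of groups on different slides rose, and 51 named values no longer passed. Furfural against HMF had 376 genes with array brightness as a covariate (the cause was not tested), 138 with only these groups fitted, which leaves fewer arrays for the variance, and 46 within slide 2, which held 1 furfural array, assumed to vary like the other group. Leaving out 1 array gave 102 to 234 genes for furfural against HMF and 203 to 366 for syringaldehyde against 4-hydroxybenzaldehyde, with fewer arrays. The other ranges were 755 to 908 for furfural, 1015 to 1333 for HMF, 1205 to 1356 for 4-hydroxybenzaldehyde, 1999 to 2020 for vanillin and 838 to 884 for syringaldehyde. The furan comparison had 1431 genes without vanillin, 1790 without 4-hydroxybenzaldehyde and 1862 without syringaldehyde.

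Of 70 tests of a list with an aldehyde, camera called 25 with the preset correlation, 16 with quantile normalization (the cause was not tested), 23 with normexp and a limited background, and 0 with an estimated correlation, by whose construction lists of correlated genes need larger shifts, with 7 at an unadjusted p under 0.05. Fry, which compares a list with no other genes, called 48. No list was set against the other genes with a symbol alone, so a shift common to those genes was not separated from these calls. Of the 417 genes that moved the same way with all 5 aldehydes, 48 did so at least 2-fold, a stricter threshold. The count was 489 with quantile normalization and 310 to 372 without 1 control array.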

Other observations

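The tests chosen only after the result was seen were both tests of consecutive identifiers.

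Genes changed at least 2-fold often carried consecutive identifiers. A run of 14 fell with all 5 aldehydes, with a median log2 fold of -3.09 with furfural, -2.77 with HMF, -3.60 with 4-hydroxybenzaldehyde, -3.08 with vanillin and -3.72 with syringaldehyde. GOX1212 belonged to a nearby run of 7 that fell with every aldehyde except HMF, where 5 of them formed the run. GOX0667 belonged to a run that rose with all 5, of 5 genes with furfural, 4-hydroxybenzaldehyde and vanillin and of 4 with HMF and syringaldehyde. GOX0691 belonged to a run of 4 that rose with 4-hydroxybenzaldehyde (median 3.52), vanillin (3.09) and syringaldehyde (3.01). The files give no positions on the genome.

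The median absolute difference of the vanillin log2 fold between 2151 pairs of consecutive numbers was 0.579, and the lowest of 1000 random pairings gave 1.01. Across genes, which are not independent replicates, the folds of consecutive numbers correlated at 0.54 to 0.68. These values describe the pattern on the folds in which it was seen, and whether such genes share their regulation was not tested. The position of the probes on the array is argued against as the source, since the median distance between probes of consecutive numbers was 67.9 spots and random pairings gave 67.7 to 68.9.

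The split of the 5 aldehydes into furans and phenolics called 1771 genes, and of the 10 splits into 2 and 3 the pair of 4-hydroxybenzaldehyde and vanillin called the most, 1852. The family of the aldehyde was thus not the division with the most called genes, and chance is not excluded for it at the level of the aldehydes. Vanillin's wide folds weigh on these counts too, so they cannot decide on family. Of the pairs without vanillin the furans called the most, followed by HMF and syringaldehyde with 1509. At least a 2-fold change was called for 197 genes by the furan split and 268 by that of 4-hydroxybenzaldehyde and vanillin.

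For the furans against the phenolics, 1 of 100 splits of the 15 treated arrays, the real one, called as many as 1771 genes, and the highest of the others called 1245. This excludes only a random grouping of the arrays, because such splits part the replicates of an aldehyde. The other 9 comparisons have 10 splits each, of which 1, the real one, called as many genes, and the share cannot go below 0.1. The real counts were 1036 for furfural, 1231 for HMF, 1499 for 4-hydroxybenzaldehyde, 2060 for vanillin, 1008 for syringaldehyde, 222 for furfural against HMF, 1734 for vanillin against 4-hydroxybenzaldehyde, 1867 for syringaldehyde against vanillin and 453 for syringaldehyde against 4-hydroxybenzaldehyde. The highest count of the other splits with limma was 1 for HMF and 0 for the remaining comparisons, with 142 to 579 genes at an unadjusted p under 0.05. Each of these splits has arrays of both groups on either side, so a difference between the groups widens the spread within a side. Low counts follow from that, and they cannot decide on chance.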
